A study of Mus musculus with 4 samples.

How the data were processed

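Expression was measured by RNA sequencing of 4 libraries of PMN-MDSCs, 2 from WT and 2 from CD300ld KO mice with B16-F10 tumours. Per the labels' protocols, cells were enriched by magnetic separation with a neutrophil enrichment kit, total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq kit. The authors deposited 1 table of whole-number read counts per gene, with no normalization applied. Per the submitters' processing notes, Bowtie 0.12.2 and the genome builds mm8 and mm9 were used, with no role given for either build. The counting program, the annotation, the strand setting and the filters are not given in the sources used here. Genes kept the symbols of the table, some of them older ones, such as Emr1, Pkm2 and Igj. Because the build is not settled, no coordinates are given, and annotation of another build (GENCODE M21) was used only for gene names, transcript lengths and the order of genes along chromosomes.

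The table held 21831 rows and 18751 distinct names. There were 205 names on several rows, up to 940 rows for U6, and all rows of a name held identical values, so each name was kept once. The number of counts did not rise with transcript length. With genes split by transcript length into 4 equal groups, the median count per gene was 38.8 in the group with the shortest transcripts and 27.0 in that with the longest. Column names gave the genotype of each library but did not tie it to 1 sample, so library numbers are only names within a genotype. No pairing was used.

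Library totals over distinct names ran from 674599 to 920839 counts. A single gene with 0 counts has an upper limit of 3 counts, which is 3.26 to 4.45 CPM in these libraries. Folds of genes with 1 to 3 counts in a genotype are ratios of summed counts with exact 95% Poisson intervals. Intervals and floors cover counting error only, since reads carried no molecular identifiers.

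Before the data were examined, the test, the gene lists, the rule for named genes and the alternatives were fixed. Counts were fitted in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr by genotype (a minimum count of 10 and a minimum total of 15), and the quasi-likelihood test of KO against WT. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM values used TMM-scaled library sizes and are given as mean ± SD of 2 libraries. The whole procedure was tested on simulated data with 200 changed genes among 7685. It recovered 32.6% of 2-fold and 79.8% of 4-fold changes, and 4.76% of its calls were false. Simulated genes were drawn independently, with a spread set by level alone, so these shares may differ in the real libraries.

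For 39 gene lists, members past the threshold were counted over all genes tested and when adjusted over the list alone. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2, and adjusted over the lists. Camera with an estimated correlation and fry, which tests whether members move on balance one way, were alternatives. The estimated form takes its p from the residual degrees of freedom of the fit, few with 4 libraries, so it has little power here. The named genes were the CD300 family, 10 fixed genes of suppressor function, up to 12 genes in each direction with the largest fitted change among called genes whose libraries did not overlap and whose mean level was in the upper 75% of tested genes, and up to 4 called members of each list by smallest p, or the 2 most abundant members of a list without calls. Names of predicted or unnamed transcripts were left out of the ranking by size. The report gives those that describe a group.

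Alternatives were RLE size factors, no scaling beyond library size, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, an added limit of 1 on the absolute log2 fold change, an adjusted p of 0.1, and leaving out each library. When a library was left out, the lone library of its genotype was assumed to vary like the others. The filter was run anew in those fits and passed 8486 to 8634 genes, against 7685 in the main fit. Lists could thus gain members of low count, and their medians may move for that reason too. Added after the data were seen were a filter of 50 CPM in 2 libraries, leaving out names on several rows, and leaving out mitochondrial and haemoglobin genes. Alternatives for normalized values and for the authors' own calls did not apply, as the table used here holds counts alone.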

Results

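RNA was measured in polymorphonuclear myeloid-derived suppressor cells (PMN-MDSCs), neutrophil-like cells that restrain T cells in tumour-bearing hosts. The cells came from C57BL/6 mice of 8 weeks that carried subcutaneous B16-F10 melanoma, a transplantable mouse melanoma line, and were collected at day 15 with a magnetic neutrophil enrichment kit. The labels do not name the organ. There were 2 libraries from wild-type (WT) mice and 2 from mice without CD300ld, a receptor of the CD300 family of myeloid cells. The deposited gene counts summed to 674599 and 920839 in the WT libraries and to 830931 and 835510 in the knockout (KO) libraries. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The counts describe a mixed preparation: erythroid markers took 15.3% to 20.9% of counts per library, secondary and tertiary granule genes 0.480% to 2.83% and B cell markers 0.735% to 1.08%. In KO, Ighm, the immunoglobulin μ chain gene of B cells, had 4487 ± 522 CPM (mean ± SD, n = 2) against 1567 CPM of S100a8. Within each genotype the libraries differed by more than sampling noise, with a chi-square per gene of 3.18 for the WT pair and 2.65 for the KO pair, against 10.1 to 10.9 for pairs across genotypes.

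Cd300ld, the targeted gene, had 0 and 11 counts in the WT libraries and 2 and 3 in the KO libraries. It lay below the filter on low counts and was not tested with the other genes. The summed ratio of KO to WT was 0.435, with an exact 95% interval of 0.119 to 1.36 that covers counting error only (exact conditional test, two-sided p = 0.136). WT library 2 held all WT counts, and without it the mean difference between KO and WT turned from −3.02 to 3.03 CPM. At this depth the targeted gene does not check the genotype labels, and the labels do not say which part of the gene was removed. Of the other family members, Cd300lb, Cd300lf and Cd300a were tested and none passed the threshold, with log2 fold changes of −1.94 ± 0.64, −0.71 ± 0.33 and −0.07 ± 0.41 (SE). Cd300a turned to 0.24 without WT library 2 and to 0.42 without KO library 2. Cd300lb had an adjusted p of 0.0908 over all genes, and 0 members were higher and 1 was lower when adjusted over the list alone. Cd300c, Cd300e, Cd300lg and Cd300lh had too few counts to test. Among 19 tested neighbours of Cd300ld on chromosome 11, 0 passed the threshold over all genes or when adjusted over the list alone. As a list they had a median of −0.28, with adjusted p = 0.107, and 0.0442 with fry.

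The comparison of KO with WT asks what the transcriptome of the PMN-MDSC preparation looks like without CD300ld. In KO libraries 16 of 20 secondary and tertiary granule genes, 6 of 7 NADPH oxidase genes and 11 of 24 type I interferon response genes were lower, and 9 of 14 erythroid markers were higher, by adjusted p in edgeR over all genes. Tests of these lists as groups passed with a preset correlation. They also passed with fry, with adjusted p = 0.0138, 0.0370, 0.0138 and 0.0397 in that order. With an estimated correlation they did not pass, and the smallest adjusted p was 0.196. That form has few degrees of freedom with 4 libraries, so its failure to call a list says little about the list. S100a8 stood at 1567 ± 2.70 CPM in KO and 11315 ± 74.6 CPM in WT (mean ± SD, n = 2 each), 7.22-fold lower in KO. S100a9, its partner in the calprotectin complex, was 6.24-fold lower. The secondary granule genes Ngp, Camp and Ltf, which encode neutrophilic granule protein, cathelicidin and lactoferrin, were 9.78-fold, 9.50-fold and 9.23-fold lower. In the other direction, Alad, an enzyme of haem synthesis, was 5.98-fold higher, and the kinase gene Pim1 rose by 3.46 on the log2 scale. For Alad and Pim1, an inherited segment of another strain and an effect of the knockout cannot be told apart.

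Of 7685 genes tested, 459 differed at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 208 higher and 251 lower in KO. The lower genes moved further. Among them 193 changed at least 2-fold and 90 at least 4-fold, against 87 and 26 of the higher genes. For all 459 genes both KO libraries lay on the same side of both WT libraries, which held for 48.2% of tested genes and is given by chance for 33.3%. In simulated libraries of this depth the same test recovered 32.6% of 2-fold changes and 79.8% of 4-fold changes, so that many changes of 2-fold would have been missed.

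**Figure D1:**
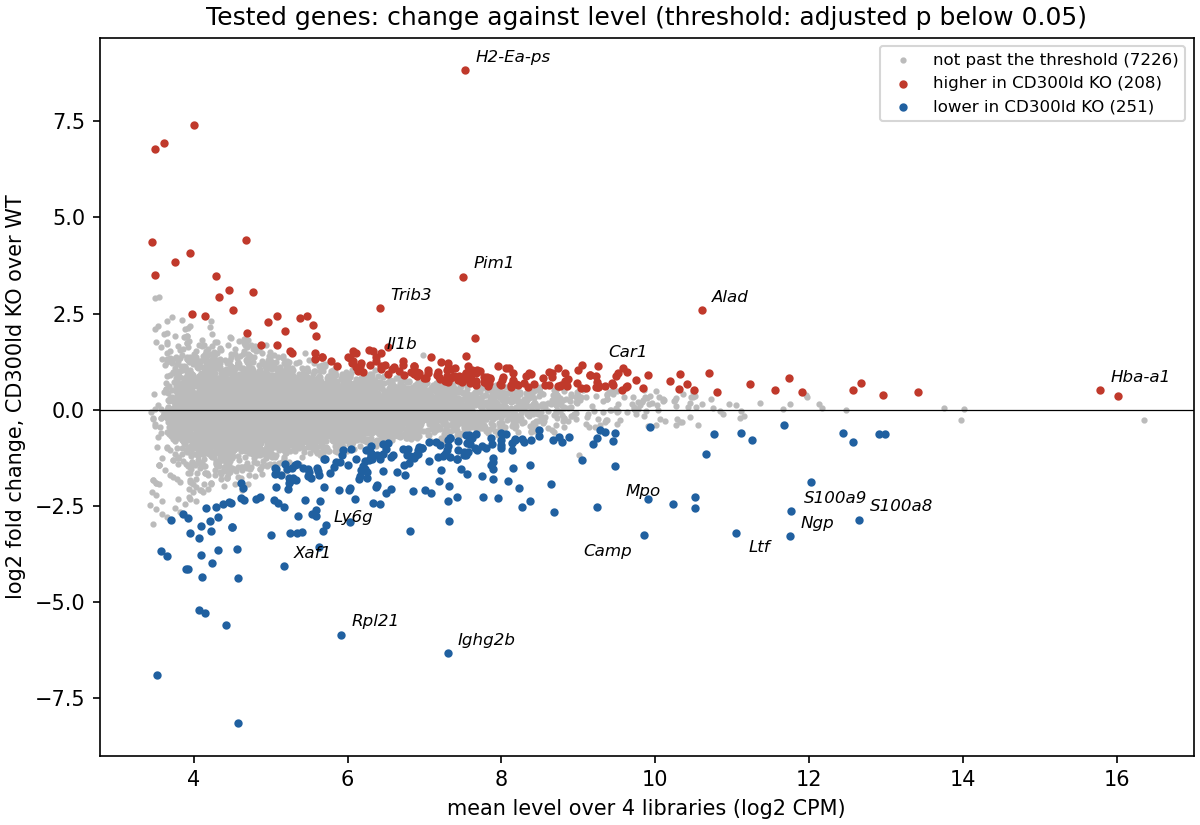
Fitted log2 fold change of KO over WT against the mean level in log2 CPM for the 7685 tested genes, with 208 higher genes in red, 251 lower genes in blue and the rest in grey. S100a8 lies at −2.85, Ngp at −3.29, Alad at 2.58 and Hba-a1 at 0.51. Fitted values of genes with no counts in a genotype depend on the prior count.

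Neutrophil precursors make secondary and tertiary granules at the myelocyte and later stages. Of the 20 tested members of that list, 16 were lower and 0 higher, with a median log2 fold change of −1.91 (17 lower when adjusted over the list alone). The list also holds the transcription factor gene Cebpe, which encodes no granule protein, and Lyz2, which monocytes and macrophages express too. Ngp fell by 3.29 ± 0.12 on the log2 scale (SE, adjusted p = 1.68e-11), Ltf fell by 3.21 ± 0.12 (adjusted p = 2.62e-11) and Lcn2, the siderophore-binding lipocalin, fell by 2.56 ± 0.13 (adjusted p = 1.45e-09). Retnlg, a member of that list, had −0.55 ± 0.17 (adjusted p = 0.0774). Its call came and went with the settings: without WT library 1 it was −0.66 (adjusted p = 0.0157) and without KO library 1 it was −0.80 (adjusted p = 0.0226). Of the 9 primary granule genes, made earlier at the promyelocyte stage, 8 were lower, with a median of −2.33 (9 lower when adjusted over the list alone). Mpo, encoding myeloperoxidase, stood at 374 ± 98.4 CPM in KO and 2032 ± 832 CPM in WT, and Elane, encoding neutrophil elastase, at 317 ± 125 and 1588 ± 519 CPM. The list tests gave adjusted p = 7.47e-40 for secondary and tertiary granules and 2.00e-16 for primary granules, and an adjusted p = 0.196 with an estimated correlation for each. In the same libraries haemoglobin genes took 16.7% of counts in KO and 13.1% in WT.

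Of 16 tested genes of mature neutrophils, 4 were lower and 1 was higher, over all genes and when adjusted over the list alone, with a median of −0.30 (adjusted p = 0.0215, and adjusted p = 0.225 with an estimated correlation). Ly6g, the surface marker of mouse neutrophils, fell by 3.14 ± 0.39 on the log2 scale and Itgam, encoding CD11b, fell by 2.11 ± 0.25. Ccrl2, an atypical chemokine receptor, rose by 1.52 ± 0.28. Csf3r, the receptor for G-CSF, had 61 and 42 counts in KO and 46 and 65 in WT, a log2 fold change of −0.17 ± 0.29 (adjusted p = 0.832). Cxcr2, which guides neutrophils out of the marrow, had −0.46 ± 0.31 (adjusted p = 0.475). Without WT library 2 the list's median was −0.16 (adjusted p = 0.0807), and without KO library 1 it was −0.51 (adjusted p = 0.00360). The sign of Csf3r turned without KO library 2, to 0.11. In the same libraries monocyte and macrophage markers had medians of −0.65 and −1.03, and erythroid markers a median of 0.42. Csf3r, Cxcr2 and Retnlg were named after their values were seen.

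**Figure D2:**
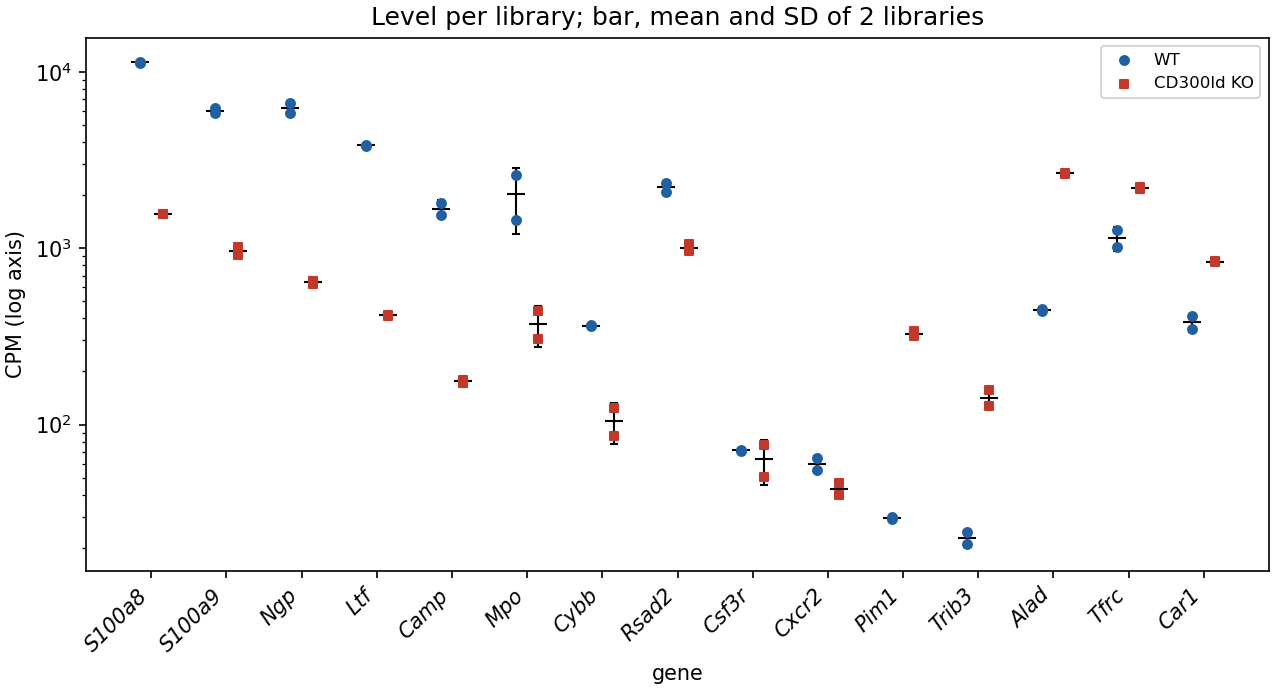
CPM on a log axis of 15 genes in each of 4 libraries, WT as blue circles and KO as red squares, with bars for the mean and SD of 2 libraries. The granule genes and the S100 pair are lower in both KO libraries, Csf3r and Cxcr2 lie close together, and Pim1, Trib3, Alad, Tfrc and Car1 are higher in both KO libraries.

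Genes tied to suppressive function went both ways. Of 9 tested effectors of PMN-MDSC suppression, 3 were lower and 1 was higher, with a median of −0.98 (adjusted p = 4.01e-05, and adjusted p = 0.225 with an estimated correlation). When adjusted over the list alone, 5 were lower and 2 higher. The median was −0.45 without WT library 1 and −0.50 without WT library 2, in fits whose filter was run anew and may have changed the members. S100a8 fell by 2.85 ± 0.10, S100a9 fell by 2.64 ± 0.11 and Mmp9, encoding gelatinase B, fell by 1.85 ± 0.19 on the log2 scale. Il1b, encoding the cytokine interleukin-1β, rose by 1.37 ± 0.28 (adjusted p = 0.00652). Cd274, encoding PD-L1, had −1.55 ± 0.58 (adjusted p = 0.147). Arg1, encoding arginase 1, had 0 counts in each WT library and 1 and 2 counts in the KO libraries, and Ptgs2, encoding cyclooxygenase-2, had 2 and 5 counts in WT and 5 and 14 in KO, both too few to test. Nos2 has no row in the table used here. In the NADPH oxidase list, which makes superoxide, 6 of 7 members were lower over all genes and when adjusted over the list alone, with a median of −1.05 (adjusted p = 3.56e-09, and adjusted p = 0.196 with an estimated correlation). Cybb stood at 105 ± 27.4 CPM in KO and 364 ± 2.15 CPM in WT, and Ncf1 at 73.8 ± 13.5 and 218 ± 12.9 CPM. Among 21 ITAM-linked and C-type lectin receptors, the class of activating myeloid receptors, 6 were lower and 0 higher over all genes, and 10 lower and 1 higher when adjusted over the list alone (median −0.81, adjusted p = 1.26e-06, and adjusted p = 0.196 with an estimated correlation). Clec5a fell by 3.26 ± 0.51 and Trem3 fell by 2.44 ± 0.28 on the log2 scale. In the same libraries monocyte and macrophage markers had medians of −0.65 and −1.03, and the granule lists −1.91 and −2.33.

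The list of JAK-STAT3 genes did not move as a group, with 2 of 17 higher and 1 lower (also when adjusted over the list alone), a median of 0.14 and an adjusted p of 0.423. The median ran from 0.04 to 0.14 when 1 library was left out, and was 0.03 with the filter of 50 CPM. Pim1, a serine kinase gene induced by cytokine signalling, rose from 29.6 ± 0.512 CPM in WT to 327 ± 15.5 CPM in KO (adjusted p = 3.39e-08). It is among the 100 tested genes nearest on chromosome 17 to H2-Ea-ps, a gene nearly absent in WT. An inherited segment of another strain and an effect of the knockout cannot be told apart for it. Junb, an AP-1 subunit, rose by 0.96 ± 0.17 on the log2 scale, and Lcn2 was the lower member. Stat3 itself had −0.50 ± 0.26 (adjusted p = 0.336) and Socs3, its feedback inhibitor, 0.36 ± 0.42 (adjusted p = 0.730).

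Of 24 tested genes of the type I interferon response, 11 were lower and 0 higher, over all genes and when adjusted over the list alone, with a median of −0.99 (adjusted p = 2.33e-12, and adjusted p = 0.196 with an estimated correlation). Rsad2, encoding the antiviral protein viperin, stood at 1009 ± 67.7 CPM in KO and 2221 ± 183 CPM in WT. Oas3, an oligoadenylate synthetase, fell by 1.72 ± 0.20 and Slfn4, of the schlafen family, fell by 3.01 ± 0.38 on the log2 scale. In the same libraries monocyte and macrophage markers had medians of −0.65 and −1.03, and the granule lists −1.91 and −2.33. Of 23 genes for antigen presentation and the interferon-γ response, 3 were lower and 0 higher, with 4 lower when adjusted over the list alone (median −0.17, adjusted p = 0.0215, and adjusted p = 0.225 with an estimated correlation; 0.0576 with the preset one when KO library 2 was left out). With the filter of 50 CPM its median was −0.27. Igtp, an interferon-inducible GTPase, fell by 2.09 ± 0.23 and H2-K1, a class I heavy chain, fell by 0.80 ± 0.14 on the log2 scale. Like Pim1, H2-K1 is among the 100 tested genes nearest to H2-Ea-ps on chromosome 17, and an inherited segment was not excluded.

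Of 19 chemotaxis and adhesion receptors, 4 were lower and 0 higher, with 4 lower and 1 higher when adjusted over the list alone (median −0.25, adjusted p = 0.0215, and adjusted p = 0.225 with an estimated correlation). Ltb4r1, the leukotriene B4 receptor, fell by 2.09 ± 0.36 and Itgb2, the β2 integrin chain, fell by 0.99 ± 0.18 on the log2 scale. Without WT library 1 that list had adjusted p = 0.0764, with the filter of 50 CPM 0.0689, and its median was −0.53 without KO library 1 and −0.50 without KO library 2. The filter was run anew in these fits, so the members behind those medians may differ. The monocyte, macrophage and granule lists, with medians of −0.65, −1.03, −1.91 and −2.33, fell in the same libraries. Of 10 chemokines and cytokines, 1 was higher (Il1b) and 1 lower (Ccl9), with a median of −0.32 (adjusted p = 0.825), which ran from −0.58 without WT library 1 to 0.01 without WT library 2. The Ccl9 call ended without WT library 1 (adjusted p = 0.0962) and without KO library 2 (adjusted p = 0.142).

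Among metabolic lists, 6 of 19 genes of glycolysis and hypoxia were lower and 0 higher, with 8 lower when adjusted over the list alone (median −0.68, adjusted p = 1.15e-06, and adjusted p = 0.196 with an estimated correlation). Eno1, encoding the glycolytic enzyme enolase, fell by 1.43 ± 0.17 and Gpi1, encoding glucose-6-phosphate isomerase, fell by 1.04 ± 0.17 on the log2 scale. In the same libraries the monocyte, macrophage and granule lists fell and erythroid markers had a median of 0.42. Of 12 mitochondrially encoded genes, 6 were lower, with 11 lower when adjusted over the list alone (median −0.60, adjusted p = 2.13e-09, and adjusted p = 0.233 with an estimated correlation). The calls of the glycolysis and mitochondrial lists were lost with fry (adjusted p = 0.0539 for each). The 20 nuclear genes of oxidative phosphorylation had 0 calls and a median of −0.12 (adjusted p = 0.106, and 0.0442 with fry). Of 14 genes of lipid uptake and storage, 2 were higher and 1 was lower, with 2 higher and 2 lower when adjusted over the list alone. Their median was 0.01 and the list test pointed upwards, while the mean was −0.10 (adjusted p = 0.847). Fabp5, a fatty acid binding protein gene, fell by 1.16 ± 0.25. The 13 apoptosis regulators and the 16 genes of NF-κB and TLR signalling had 0 calls each, with medians of −0.06 and −0.10 (adjusted p = 0.858 and 0.825). When 1 library was left out, the apoptosis median ran from −0.06 to 0.05 and the NF-κB and TLR median from −0.23 to 0.08. The lipid median turned sign whichever library was left out, to between −0.03 and −0.02, and was 0.10 with the filter of 50 CPM. The filter was run anew in each of these fits, so a change of members may account for such shifts. Of 72 ribosomal protein genes 2 were lower, Rpl21 and Rps18, with a median of 0.12 (adjusted p = 0.198), which was 0.02 with the filter of 50 CPM. Rps18 is also among the 100 tested genes nearest to H2-Ea-ps on chromosome 17.

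**Figure D3:**
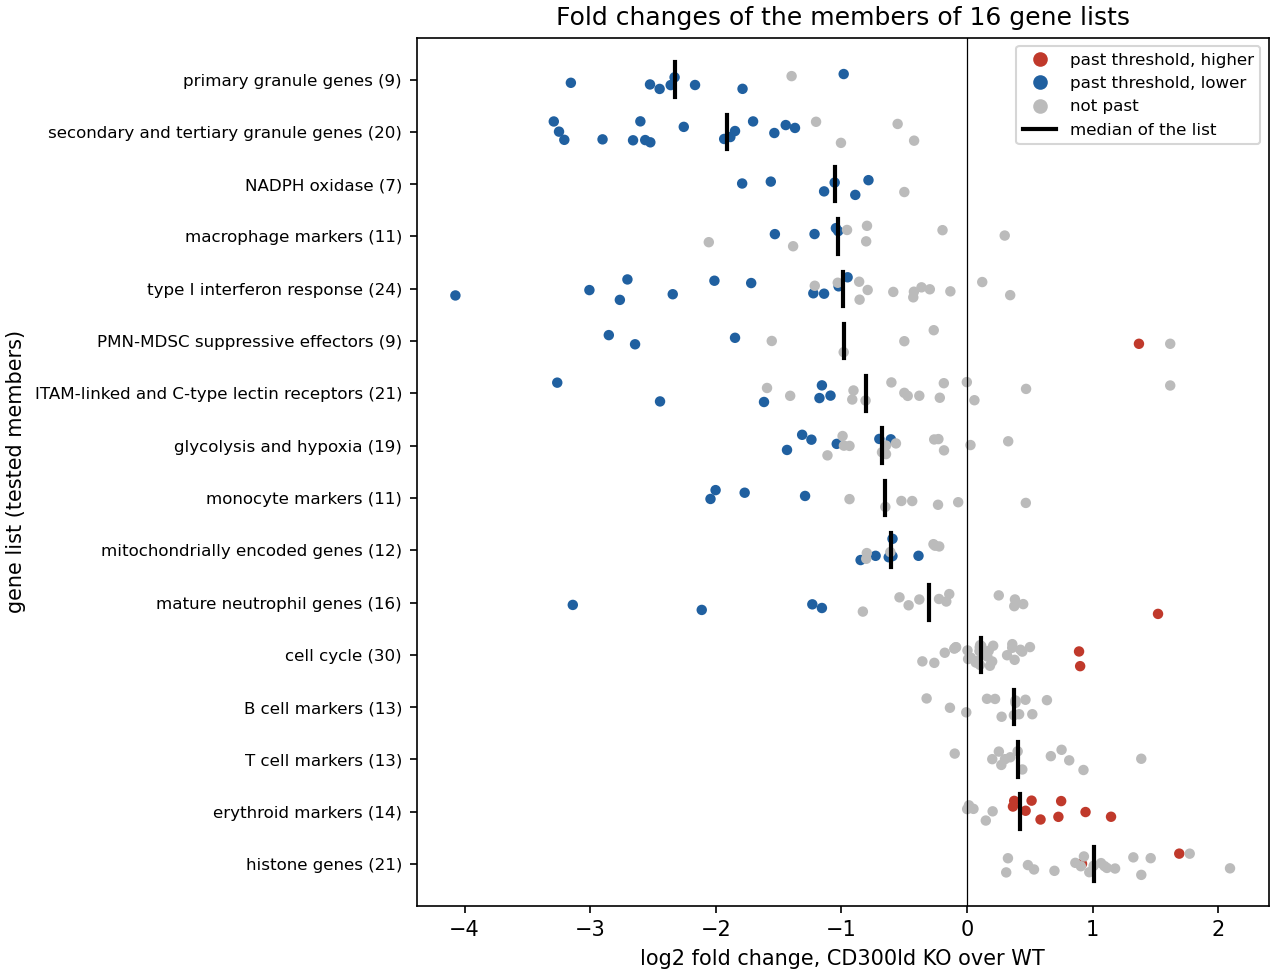
Log2 fold change of KO over WT for each tested member of 16 gene lists, with list sizes in brackets, called members in colour, the rest in grey, and a black bar at the median. Primary granule genes have the lowest median, −2.33, mature neutrophil genes lie near 0 at −0.30, and erythroid markers and histone genes lie at 0.42 and 1.01.

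Markers of other cell types moved in both directions. Haemoglobin genes took 16.7 ± 0.826% of counts in KO and 13.1 ± 0.892% in WT, and secondary and tertiary granule genes 0.496 ± 0.0225% and 2.68 ± 0.215% (mean ± SD, n = 2 each). Of 14 erythroid markers, 9 were higher and 0 lower, over all genes and when adjusted over the list alone, with a median of 0.42 (adjusted p = 1.06e-09, and adjusted p = 0.225 with an estimated correlation). Car1, encoding a carbonic anhydrase of erythroid cells, was 2.21-fold higher and Tfrc, the transferrin receptor, 1.92-fold higher. Hba-a1 rose by 0.51 ± 0.08 on the log2 scale, and its near-identical copy Hba-a2 had 0.05, so that their separate counts are uncertain. Monocyte markers were lower in 4 of 11 cases, over all genes and when adjusted over the list alone (median −0.65, adjusted p = 1.47e-05, and adjusted p = 0.225 with an estimated correlation), and Ly6c2 had a log2 fold change of −2.04 ± 0.21. The monocyte median was −1.32 with the filter of 50 CPM, and fry gave adjusted p = 0.0644. Macrophage markers were lower in 4 of 11 cases, with 9 lower when adjusted over the list alone (median −1.03, adjusted p = 7.08e-06, and adjusted p = 0.196 with an estimated correlation), and Vcam1 had a log2 fold change of −1.21 ± 0.22. B and T cell markers had 0 calls each, over all genes or when adjusted over the list alone, and medians of 0.37 and 0.40 (adjusted p = 0.00817 and 0.0215, and adjusted p = 0.225 with an estimated correlation for each). Without WT library 1 the B and T cell list tests gave adjusted p = 0.127 and 0.178, with a B cell median of 0.21. The B cell median was also 0.21 without KO library 1 and the T cell median 0.64 without WT library 2, and without KO library 2 the T cell list gave 0.0770. With fry the B and T cell lists gave 0.0539 and 0.0541. Dendritic cell markers had 1 of 9 higher over all genes, and 1 higher and 1 lower when adjusted over the list alone. Their median was −0.17 (adjusted p = 0.825), which ran from −0.24 to 0.03 when 1 library was left out. The higher one was Siglech, of plasmacytoid dendritic cells, and its call ended without WT library 2 (adjusted p = 0.0807) and without KO library 2 (adjusted p = 0.223). Lists with under 5 tested members had no list test. Among these, 1 of 3 plasma cell markers was higher (Igj, with adjusted p = 0.0977 and 0.140 without KO library 1 or 2), 1 of 2 basophil and mast cell markers was lower (Hdc, encoding histidine decarboxylase), and 0 of 4 NK cell, 0 of 2 eosinophil, 0 of 2 platelet and megakaryocyte and 0 of 2 stem and progenitor markers passed the threshold. Adjusted over the list alone, 2 plasma cell markers were higher and 1 eosinophil marker was lower. The only sex-linked gene tested, Xist, was counted in all 4 libraries, with a log2 fold change of 0.41 ± 0.19 (adjusted p = 0.248). Melanoma markers and stromal, endothelial and epithelial markers had 0 members with enough counts to test.

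Histone genes were higher as a list, with 2 of 21 higher, 6 when adjusted over the list alone, and a median of 1.01 (adjusted p = 3.98e-07, and adjusted p = 0.214 with an estimated correlation). Hist1h1c, a linker histone gene, rose by 0.92 ± 0.21 on the log2 scale (adjusted p = 0.0118), and without KO library 1 it was 0.83 (adjusted p = 0.0574). Their near-identical copies make single members uncertain. Of 30 cell cycle genes 2 were higher, also when adjusted over the list alone, with a median of 0.11 (adjusted p = 0.0244, and adjusted p = 0.439 with an estimated correlation). Mki67, the proliferation marker, rose by 0.90 ± 0.13. Leaving out WT library 2, KO library 1 or KO library 2 ended the call of the cell cycle list, with adjusted p = 0.285, 0.0627 and 0.0618, as did the filter of 50 CPM (0.101) and fry (0.192). Its median was 0.23 without WT library 1 and 0.06 without WT library 2. In the same libraries 9 of 14 erythroid markers were higher, with Car1 at 1.15 ± 0.14, Tfrc at 0.94 ± 0.13 and Rhd at 0.75 ± 0.12 on the log2 scale.

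Of 16 genes of the ER stress list, 4 were higher and 2 lower, 5 and 4 when adjusted over the list alone. The median was −0.31 while the mean was 0.15 and the list test pointed upwards (adjusted p = 0.825). That median ran from −0.34 to −0.01 when 1 library was left out. Trib3, a pseudokinase gene induced by the transcription factor ATF4, rose by 2.64 ± 0.29 on the log2 scale, Ddit3, encoding CHOP, by 1.55 ± 0.27 and Ppp1r15a, encoding GADD34, by 0.93 ± 0.13. Atf4 rose by 0.63 ± 0.15 (adjusted p = 0.0190), while the chaperone gene Calr fell by 0.69 ± 0.16 and the chaperone gene Hspa5 fell by 0.57 ± 0.13. Without WT library 1, KO library 1 or KO library 2, Atf4 had adjusted p = 0.102, 0.0701 and 0.0762. Hspa5 had 0.107 and 0.0925 without KO library 1 or 2, and Calr 0.0529 and 0.0598 without WT library 2 or KO library 2. Atf4 and Hspa5 were named after their values were seen. Immediate early and heat shock genes were higher in 2 of 17 cases, with 5 higher and 3 lower when adjusted over the list alone (median 0.28, adjusted p = 0.0475, and adjusted p = 0.612 with an estimated correlation). That list's call ended without WT library 1 (median 0.03, adjusted p = 0.878) and without KO library 2 (adjusted p = 0.166), and its median was 0.56 without WT library 2. With fry it gave adjusted p = 0.507, and with either exclusion of genes 0.0501 and 0.0520.

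Some called genes had almost no counts in 1 genotype. H2-Ea-ps, annotated as a pseudogene of the class II α chain gene H2-Ea, had 274 and 313 counts in KO and 0 and 1 in WT, a ratio of 562 with an exact 95% interval of 100.5 to 22240. Rpl21, a ribosomal protein gene with many processed copies and therefore uncertain, had 2 and 1 counts in KO and 71 and 109 in WT, 62.7-fold lower with an interval of 21.1 to 307. Ighg2b, an immunoglobulin constant region gene, had 0 and 6 counts in KO and 321 and 123 in WT (adjusted p = 3.15e-05 in edgeR, and adjusted p = 0.153 in limma-voom).

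The list tests compared each list with all other genes, with a preset correlation. They called 19 of 29 testable lists, 6 higher and 13 lower, and 0 lists with a correlation estimated per list, whose smallest adjusted p was 0.196. Fry, which tests members against no change, called 14.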

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

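The filter of 50 CPM and both exclusions of genes were chosen after the data were seen. The count of 459 genes became 280 with a limit of 1 on the absolute log2 fold change, with 87 of them higher, and 700 at an adjusted p of 0.1, with 331 of them higher; both follow from how these thresholds are built. The 19 called lists became 0 with an estimated correlation. A correlation above the preset 0.01 does not account for every loss. The estimate was −0.017 for ITAM-linked and C-type lectin receptors, −0.093 for macrophage markers and −0.063 for T cell markers. It lay above the preset for other lists, such as mitochondrially encoded genes (0.589). With an estimated correlation, camera also takes its p from the residual degrees of freedom, which are few with 4 libraries. The unadjusted camera p went from 3.91e-07 to 0.0308 for ITAM-linked and C-type lectin receptors. For macrophage markers it went from 2.44e-06 to 0.0385. How far each part lowered the calls was not tested. Fry gave 14 lists, with 7 calls lost (cell cycle, glycolysis and hypoxia, immediate early and heat shock, T cell, B cell, monocyte and mitochondrially encoded genes) and 2 gained (oxidative phosphorylation and the neighbours of Cd300ld). The filter of 50 CPM left 24 lists with enough members to test and gave 14, with 2 calls lost (chemotaxis and adhesion receptors, and cell cycle); the called lists of suppressive effectors, T cell markers and histone genes had no test there. Keeping named genes in the windows around H2-Ea-ps and Alad, also chosen after the data were seen, moved the odds ratios from 0.591 to 0.990 and from 1.23 to 1.17. Leaving out 1 library gave 412 to 538 genes, 165 to 238 higher and 216 to 300 lower, and 15 to 18 lists. Between 84 and 134 of the 459 calls were lost in those fits, and none turned sign. All other settings gave between 397 genes (DESeq2) and 564 (50 CPM in 2 libraries). The filter of 1 CPM lies below 1 count at this depth and was looser than the filter used, with 14053 genes tested and 423 called. Over named genes and settings, 1911 values kept their side of the threshold, 117 lost it and 16 gained it. For list tests the counts were 241, 41 and 2. No called gene's fold change and no called list's median turned sign, while 13 values of uncalled genes and 11 medians of uncalled lists did. No paired analysis was possible because the sample titles share no number between genotypes and columns could not be tied to samples. The comparison with the authors' own calls was not run, since the table used here holds none. Depth limits genes such as Cd300ld, whose difference of −3.02 CPM ranged from −9.19 to 3.03 when 1 library was left out.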

Other observations

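The tests of explanations below were chosen after the pattern was seen; the tests of chromosome neighbours and of further ATF4 targets had their outcome predicted before those genes were looked at.

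Some haem synthesis genes were looked at after Alad was seen, with no list fixed or tested. Ppox had a log2 fold change of 0.92 (adjusted p = 0.00173), Uros 0.85 (adjusted p = 0.00706), Urod 0.55 (adjusted p = 0.00917) and Cpox 1.07 (adjusted p = 0.0144). Without KO library 2 Uros had adjusted p = 0.0768, without KO library 1 Urod had 0.113, and Cpox had 0.107 and 0.0623 without WT library 2 or KO library 2. Alas2, also an erythroid marker, and Fech had 0.00 (adjusted p = 0.997) and −0.03 (adjusted p = 0.931). Some immunoglobulin genes, picked after the data were seen and with no list tested, went apart. Ighg2c had 59 counts in WT and 1 in KO. Ighv1-9 had 65 counts in WT and 0 in KO, at least 22.6-fold lower with a floor of 3 counts over the group. Ighm and Igkc did not pass the threshold in edgeR, with log2 fold changes of 0.37 (adjusted p = 0.0755) and 0.16 (adjusted p = 0.577). Igj, the joining chain gene of plasma cells, rose by 0.56 on the log2 scale, a call lost without KO library 1 or 2 (adjusted p = 0.0977 and 0.140).

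Most granule genes were lower in KO. A rise of every other cell type alike does not account for it. The median of monocyte and macrophage markers differed from that of erythroid, B and T cell markers by −1.33 (permutation of genes, two-sided p = 1.00e-05, the smallest the permutations can give). That permutation treats genes as independent, and it does not address a rise of erythroid, B and T cells alone. A loss of neutrophils of every stage alike would lower mature neutrophil genes as far, and the medians of 29 granule and 16 mature neutrophil genes differed by −1.86 log2 units, but Ly6g fell by 3.14 and several of these genes are also expressed by other leukocytes of a mixed preparation, so the values do not exclude it. Fewer granule-making precursors in KO, lower granule transcription per cell and an unequal enrichment of cells by the kit may each contribute and stay open, as untested.

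H2-Ea-ps was nearly absent in WT, and Alad was 5.98-fold higher in KO. More antigen-presenting cells would have raised H2-Aa, H2-Ab1, H2-Eb1 and Cd74, whose largest log2 fold change was 0.17. More erythroid cells of an unchanged profile would have raised Alad no further than erythroid markers. It exceeded Car1, the marker that rose most, by 1.43 log2 units (range of 2 SE, 1.06 to 1.81). The erythroid markers did not move alike, with log2 fold changes from 0.00 to 1.15, so a changed erythroid component is not excluded. H2-Ea is silent in mice of the b haplotype such as C57BL/6, and a candidate explanation is that the KO mice carry segments of another strain. With named genes left out, calls were not denser among the 100 nearest tested genes to H2-Ea-ps on chromosome 17 (3 of 100, odds ratio 0.591, 95% interval 0.119 to 1.79, Fisher's exact p = 0.488). Nor were they denser near Alad on chromosome 4 (6 of 100, odds ratio 1.23, interval 0.437 to 2.81, Fisher's exact p = 0.638). A test added after the first was seen kept named genes such as H2-K1, Rps18 and Pim1. It gave 6 and 7 of 100, with odds ratios of 0.990 (interval 0.352 to 2.26) and 1.17 (interval 0.455 to 2.53). With so few calls per window these tests cannot decide, since genes of an inherited segment need not differ in expression. A silent b haplotype would give H2-Ea-ps few counts, so its 274 and 313 counts in KO argue against a knockout effect alone at this gene. For Alad and other genes, inherited segments and effects of the knockout cannot be told apart.

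Trib3, Ddit3 and Ppp1r15a, genes linked to ATF4, rose in KO, which led to the hypothesis that other ATF4 targets rise too. Of 27 targets listed before they were looked at, 20 were tested, 17 had a positive log2 fold change and 6 were past the threshold, all higher, with a median of 0.54 (0.539; permutation p = 5.80e-04 against random tested genes). Trib3 exceeded Car1, the erythroid marker that rose most, by 1.498 log2 units (range of 2 SE, 0.849 to 2.15). It was set apart from the genes below after its value was seen. The erythroid markers did not move alike, with log2 fold changes from 0.00 to 1.15, so this excess does not exclude an erythroid source. Among Ddit3, Atf4 and Ppp1r15a the largest excess over Car1 was 0.40 (0.399; range of 2 SE, −0.21 to 1.01), and the other targets exceeded erythroid markers by 0.12 (0.118; permutation p = 0.439). For Trib3 and these genes, erythroid RNA and a stress response in KO cells cannot be told apart. Stress during cell isolation was not settled either. Immediate early and heat shock genes had a median of 0.03 without WT library 1 and 0.56 without WT library 2.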
